A study of Mus musculus with 4 samples.

How the data were processed

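Messenger RNA was measured on 4 Agilent mouse 8x60K arrays with 1 colour, 1 array for each combination of genotype and treatment. Per the labels, vascular smooth muscle cells of passages 12 to 16 were grown from 5 aortas, and the RNA on an array was pooled from a triplicate. Each group was therefore 1 pooled sample, so no spread between biological replicates could be measured and no test between groups was run. Of the total RNA, 1 µg was labelled and 0.6 µg of labelled RNA was hybridised, per the labels.

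The deposited scanner files held a spot intensity on a linear scale for 62976 spots per array, made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity was already background-subtracted by that software, per the file headers. The authors' deposited value table held a linear signal as well. Its columns had medians of 57.6, 57.6, 57.5 and 57.4 and followed the median spot signal of the same arrays in rank and level, without background subtraction. The submitters' processing notes name RMA and oligo, with versions not given in the sources used here, while the table's values are not on a log scale. How its between-array scaling was computed stays unknown.

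Control spots and spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged as log2 values. This gave 55679 probes. From each array the 75th percentile over these probes was subtracted. A probe name was turned into a gene through its RefSeq accession, without the version, in a gene table of the mouse assembly GRCm38.p6. The files name another build, so no coordinates are given. Of 55679 probes, 28330 matched 1 gene and none matched several, which gave 21367 genes, and 27349 probes stayed unnamed. A gene was represented by its probe with the highest mean over the arrays, and 5754 genes had several probes. A gene entered a comparison if that probe was well above background on every array compared.

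Differences are log2 values of one array minus another. Before the data were examined, the design fixed 5 comparisons, 28 gene lists, 9 lists of cell type markers and the rule for naming genes. That rule took the 10 highest and 10 lowest differences of at least 2-fold, if also at least 2-fold after a second background correction and normalisation. It added up to 4 members of a list that stood apart, with Lamp2 and Hspa8 in every comparison, and up to 5 genes per direction that were above background on 1 array only. The text names part of the genes this rule took, and some of them are not reported here. Interferon list members and other probes below background on 1 array were added after their values were seen. A list's median was set against 10000 random lists of the same size matched on mean level in 20 bins, and stood apart outside their central 95%. This percentile describes these arrays and is not a test of the condition. Members of a list were counted as higher or lower at 1.5-fold. A gene could be on several lists, so the lists are not independent of each other. A gene below background on one array has only a bound, its bright value over the higher of the dim value and the lowest value well above background on the dim array.

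The alternatives were 4 other scalings, a normexp background correction with an offset of 50 and quantile normalisation, the authors' deposited values, 3 other filters on dim probes, and the mean over a gene's probes. The normexp correction used the median spot signal, because the files used here hold no mean signal. Removal of the dimmest 25% of measured genes was added after the data were seen. Spots printed 10 times on an array, for 399 probes, gave a median SD of at most 0.054 in log2 units among probes well above background. This covers technical spread within an array only, and gives 0.08 for a difference of 2 spots.

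The steps were tested on simulated data made from the WT control array for the comparison of LDL with control in WT, over 12978 genes. Of 50 genes given a 2.5-fold difference 50 were called, of 50 given 4-fold 50 were called, and of 50 given 1.8-fold 3 were called. With noise at the spread between repeated spots alone (SD 0.08), 0 unchanged genes were called. A 2-fold difference lies far outside such noise, so this could not measure false calls between real arrays. The real differences of this comparison had an SD of 0.30. The list step was tried on the real differences of this comparison instead. Of 200 random lists of 25 genes drawn from them, 9 stood outside the central range, and all 200 did so above it once each member was moved by 0.3. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.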

Results

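Gene expression was measured in cultured mouse aortic vascular smooth muscle cells, either wild type (WT) or lacking LAMP-2A (L2AKO). LAMP-2A is the lysosomal receptor of chaperone-mediated autophagy, which delivers single proteins to the lysosome with the help of the chaperone Hspa8. Both lines were kept for 24 h in medium with 5% lipoprotein-deficient serum, with or without LDL at 150 µg/ml cholesterol together with 0.1 U/ml lipoprotein lipase. Whether the cells without LDL received the lipase is not given in the sources used here. Each of the 4 groups had 1 array, so differences below carry no replicate error and no p-value.

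The 75th percentile of the processed signal was 318.8 for WT control, 370.6 for WT LDL, 389.4 for L2AKO control and 433.8 for L2AKO LDL. Probes well above background made up 47.2%, 48.4%, 47.2% and 52.0% of the arrays in that order, and no spot was saturated. The L2AKO LDL array lay on a second slide, scanned apart from the other 3. Of 8 spike-in controls measured on all arrays, 7 lay outside the range of the other 3 arrays on the L2AKO LDL array, by -1.16 to 0.62 log2 units from their mean. The spike-ins of the other 3 arrays ranged over at most 0.51. Every comparison that uses the L2AKO LDL array therefore also compares slides, and slide and group cannot be told apart there.

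**Figure D1:**
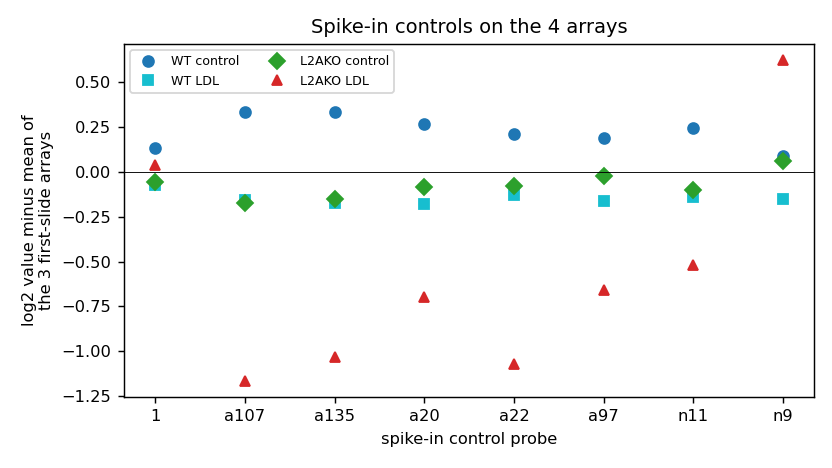
Normalised log2 values of 8 spike-in control probes (x axis) on each of the 4 arrays, minus the mean of the 3 arrays on the first slide (y axis, log2 units). The L2AKO LDL array lies outside the range of the others for 7 of the 8 probes, from -1.16 to 0.62.

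Lamp2 was the targeted gene and had 2 probes. One differed little, with normalised log2 values of 6.29 in WT control, 6.38 in WT LDL, 6.33 in L2AKO control and 6.09 in L2AKO LDL. The other read 3.68, 3.74, 2.30 and 2.41 in the same order, so Lamp2 was lower in L2AKO on this probe by 1.38 log2 units without LDL (log2 difference -1.38) and by 1.32 with LDL (-1.32). Which probe lies in the deleted part of the gene is not given in the sources used here, so whether either probe tests the deletion stays unknown. Hspa8 had 3 probes, which differed between genotypes without LDL by 0.00 on the brightest and by 0.02 and 0.56 on the others. With LDL these probes of Hspa8 were 0.76, 0.46 and 0.48 higher in L2AKO, values taken across slides.

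The first comparison asked how WT cells responded to LDL. Genes of cholesterol synthesis and uptake were lower with LDL for 25 of 26 measured members, with a list median of -2.13, below all 10000 random lists. Idi1 was 7.36-fold lower, Fdps, which makes farnesyl diphosphate, was 6.58-fold lower and Mvd, the mevalonate diphosphate decarboxylase, was 6.57-fold lower. Fatty acid synthesis followed with 8 of 15 members lower and a median of -0.72, among them Elovl6 (-1.97), Acss2 (-1.44) and Fasn (-1.22).

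Interferon response genes formed the next group in WT, with 22 of 29 measured members lower with LDL, none higher and a median of -1.32, below all random lists. Usp18 (-3.36), Rtp4 (-3.32), Isg15 (-3.22) and Oasl2 (-3.18) led the list. Antigen presentation genes had a median of -0.55, with 5 of 13 lower, including the immunoproteasome genes Psmb8 (-1.38) and Psmb9 (-1.10). Psmb8, Psmb9 and Tap1 are on the interferon list too. Of 25 inflammation and chemokine genes, 12 were lower and none higher (median -0.50), led by the acute phase gene Saa3 (-4.39) and by Lcn2 (-4.05), with Cxcl5 at -1.68 and Cxcl1 at -1.65. Outside the lists fixed beforehand, Saa1 differed by -3.85 and the nucleic acid sensor Zbp1 by -3.13.

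Few genes were higher with LDL in WT. The glutathione S-transferases Gsta2 (2.04), Gsta4 (1.79) and Gsta3 (1.29) led the NRF2 and oxidative stress list, of which 4 of 34 members were higher and 1 lower. Angptl4, an inhibitor of lipoprotein lipase, was 1.06 higher and Dhrs3 1.08 higher. Krtap1-4, a hair keratin-associated gene, stood at 2.07. Krtap1-4 (-3.30) and Gsta2 (-3.19) were dim in WT control, where the lowest normalised value well above background was -4.23. A further list held targets of the sterol receptor LXR together with cholesterol efflux genes. On this LXR and efflux list, Abca1, which exports cholesterol, was 0.89 higher and Ch25h 1.50 lower (log2 difference -1.50). Abcg1, also on it, was not well above background on any array. The list median of -0.13 stayed inside the random range. Lipid droplet genes (median -0.04) and contractile smooth muscle genes (median -0.07) stayed inside it as well, and Acta2 differed by -0.18.

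Across 12978 measured genes, 32 were at least 2-fold higher with LDL in WT and 133 at least 2-fold lower. Higher genes made up 19.4% of these, against 8.7% after normexp, 9.5% in the authors' deposited values and 42.2% among genes above background on at least 1 array. Of 37 lists, 15 stood outside the random range. Above background on 1 of the arrays only were Ccn6, at least 35.7-fold higher with LDL, and Saa2, at least 7.68-fold lower.

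The second comparison asked how L2AKO cells responded to LDL, and sterol genes were lower there as well. Of 27 members of the cholesterol list, 26 were lower (median -1.83, below all random lists), among them Idi1 at 13.2-fold lower, Fdps at 9.10-fold lower and Hsd17b7 at 6.45-fold lower. Fatty acid synthesis genes had a median of -0.65, with Elovl6 at -2.48 and Acss2 at -1.24. Inflammation and chemokine genes had 13 of 23 members lower and a median of -0.90, with Saa3 at -3.58, Lcn2 at -3.54, Cxcl5 at -2.41 and Il6 at -1.89.

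Interferon response genes were lower in L2AKO with LDL for 15 of 30 members and higher for 1 (median -0.58, below all random lists), with Oasl1 at -1.19, Rtp4 at -1.15 and Ifit1 at -1.08. Gsta2 (1.84) and Nqo1 (1.06) were higher, and the superoxide dismutase Sod2 was lower (-1.14). TGF-beta and BMP signalling genes had a median of -0.28, with Ltbp2 at -1.38 and the BMP antagonist Nog at -1.14. Ribosomal protein genes had a median of 0.14, led by Rpl4 (1.03), but this median was below 0 after quantile normalisation and after normexp. Iqsec3 (3.58), Oas1d (2.28), Cox17 (1.85), Tlr7 (1.83) and the taste receptor gene Tas2r113 (1.75) were the highest of the named genes above background on both L2AKO arrays. Oas1d (-3.46) and Cox17 (-3.15) were dim in L2AKO control, where the lowest normalised value well above background was -4.45. Slc2a2, above background with LDL only, was at least 15.7-fold higher.

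Of 13008 genes, 121 were at least 2-fold higher with LDL in L2AKO and 173 lower, on arrays of different slides, and 12 of 37 lists stood outside the random range. Higher genes made up 41.2%, against 55.7% with median scaling, which moved the median of all genes by 0.11, 53.6% when scaled over probes above background on all arrays and 32.7% with no filter on dim probes. Other probes of the same genes agreed unequally. Of 13 other probes of the higher genes, 2 were at least 1.5-fold higher, whereas 18 of 22 other probes of the lower genes were at least 1.5-fold lower.

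**Figure D2:**
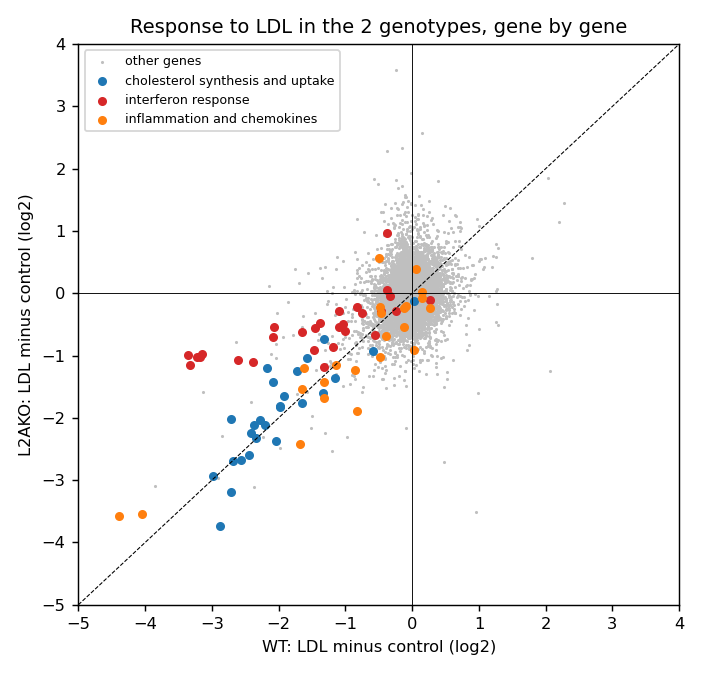
Each point is a gene well above background on all 4 arrays, with its LDL minus control difference in WT on the x axis and in L2AKO on the y axis (log2 units); the dashed line marks equal values. Cholesterol genes (blue) lie near the line at list medians of -2.13 and -1.83, while interferon genes (red) reach -3.36 in WT and lie above the line.

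The LDL responses of the lines correlated with r = 0.34 (Spearman rho = 0.15) across 12492 genes above background on all arrays. Genes are not independent replicates, and the 2 responses share no array. Among these genes 119 were lower in WT and 138 in L2AKO, with 60 in common against 1.31 for independent lists. For higher genes the counts were 24 and 105, with 4 in common against 0.20.

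The genotypes without LDL were compared on 1 slide. Cell cycle and mitosis genes were lower in L2AKO for all 27 measured members, with a median of -2.76, below all random lists. Nusap1 (-3.71), Prc1 (-3.55), Ccnb1, the mitotic cyclin B1 (-3.52), and the mitotic kinase Plk1 (-3.42) were lowest, and the proliferation marker Mki67 was at -3.36. DNA replication genes were lower for 28 of 36 members (median -1.24), with Mcm10 at -3.09, Tk1 at -3.07 and Mcm5 at -2.92. Of 37 p53 target and apoptosis genes, 15 were lower and 2 higher (median -0.39), and Perp, a desmosomal membrane protein, differed by -8.00.

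Sterol genes also differed between the genotypes without LDL. Cholesterol synthesis and uptake genes were lower in L2AKO for 14 of 27 members (median -0.69), with Hsd17b7 at -1.44 and Dhcr7 at -1.35. The LXR and efflux list was higher for 6 of 13 members and lower for 1 (median 0.49, percentile 99.39), including Ch25h (13.5-fold), Apoe (8.23-fold) and Abca1 (3.62-fold).

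Among the named genes above background on both arrays, the lowest after Perp were Cck (-6.22), Slc24a3 (-6.21) and the activin antagonist Fst (-6.08). The highest of them were type III collagen, Col3a1 (6.15), and the receptor genes Adora2b (5.79) and Adcyap1r1 (5.64). Among matrix genes, Ccn3 was 5.56 higher in L2AKO, the collagen-degrading cathepsin Ctsk was 4.55 higher and Mmp2 was at -3.94. Matrix turnover genes had a median of 0.52. Contractile smooth muscle genes went both ways (median -0.33), with Tagln at 1.27 and Cnn1 at 1.11 against Actg2 at -1.73, while Myh11 was not well above background on any array. Adventitial fibroblast markers were higher for 8 of 15 members and lower for 4 (median 0.85), with Serpinf1 at 4.28 and Pi16 at 4.14, but their median was -0.08 among genes above background on all 4 arrays. Mesothelial and epithelial markers were lower for 5 of 7 members and higher for 2 (median -1.62), with Cdh1 at -3.14 and Msln at -2.31 against Lrrn4 at 3.40. Macrophage markers were mixed (median -0.02), with Trem2 at 3.39 and Cd68 at 1.85 but Lgals3 at -1.47.

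Chaperone-mediated autophagy genes had a median of 0.22 (percentile 98.84), with 5 of 21 higher and 1 lower, led by Phlpp1 (1.42). Lysosome genes had a median of 0.13, with 12 of 53 higher and 8 lower, among them Ctsk and, in the other direction, Cln3 (-2.01). Macroautophagy genes stayed inside the random range (median 0.02). Inflammation genes had a median of -0.28, between -0.54 and -0.02 over the alternatives, with Cxcl5 at -3.34 and Ptgs2, the inducible cyclooxygenase, at -3.02 against Ccl8 at 3.02. Interferon genes stayed inside the random range (median 0.11), though Oas1a was 2.83 higher and Cxcl10 stood at -2.34. Of the sex-linked genes, Xist was not well above background on any array, and Ddx3y and Eif2s3y, both on the Y chromosome, were measured on all 4.

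Of 12594 genes, 952 were at least 2-fold higher and 1034 at least 2-fold lower in L2AKO without LDL, and 16 of 37 lists stood outside the random range. Above background on 1 array only were Ebf3, at least 109-fold higher in L2AKO, and Sfrp2, at least 465-fold lower. With 1 line per genotype, the values compare these lines. Among other probes of the same genes, 181 of 207 were at least 1.5-fold higher and 176 of 205 at least 1.5-fold lower, each on the side of the gene.

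**Figure D3:**
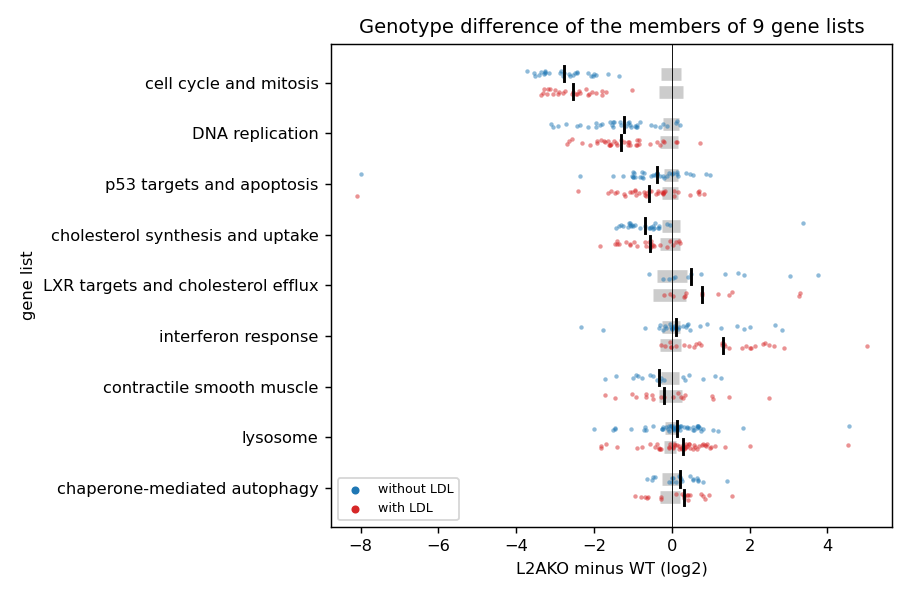
L2AKO minus WT differences (x axis, log2 units) of the measured members of 9 gene lists (y axis), without LDL in blue and with LDL in red. Black bars mark list medians and grey bands the central 95% of random list medians. All cell cycle members lie below 0, and the interferon median is 0.11 without LDL and 1.33 with LDL.

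With LDL the lists of cell cycle, DNA replication, cholesterol, and LXR and efflux genes lay on the side they had without LDL. Cell cycle genes were lower for 27 of 27 members (median -2.53), with Nusap1 at -3.36 and Kif11 at -3.32, and DNA replication genes for 29 of 37 (median -1.30). Cholesterol genes had a median of -0.57, with 12 of 26 lower, and LXR and efflux genes a median of 0.76, with Apoe at 3.28 and Ch25h at 3.29. Col3a1 was 8.43 higher and Perp differed by -8.10.

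Interferon genes stood apart between the genotypes once LDL was present. Of 28 measured members, 19 were higher in L2AKO and none lower (median 1.33, above all random lists), led by Oas1a (5.02), Psmb8 (2.89), Oasl2 (2.62) and Psmb9 (2.49). Outside this count, among members below background on 1 of the arrays, Cxcl10 was at -3.56 or lower and Oas2 at 3.80 or higher. Antigen presentation genes, which share Psmb8, Psmb9 and Tap1 with the interferon list, had a median of 0.63, with 7 of 13 higher. Inflammation genes were lower in L2AKO for 12 of 23 members and higher for 5 (median -0.68), with Cxcl5 at -4.07 and Ptgs2 at -3.52 against Ccl8 at 3.44 and Saa3 at 2.30. Lysosome genes had a median of 0.28 and chaperone-mediated autophagy genes a median of 0.32, with 5 of 21 higher and 5 lower.

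Of 12936 genes, 1073 were at least 2-fold higher and 1341 lower in L2AKO with LDL, across slides, and 15 of 37 lists stood outside the random range. Higher genes made up 44.4%, against 60.0% with median scaling, which moved the median of all genes by 0.20. The genotype differences without and with LDL, which share no array, correlated with r = 0.92 (rho = 0.84) across 12492 genes. In common were 737 of the higher genes, against 77.1 for independent lists, and 876 of the lower genes, against 97.8.

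The last comparison set the LDL response of L2AKO against that of WT. Interferon response genes had the largest median of the 37 lists in the main setting, with 15 of 28 at least 1.5-fold higher in the difference of responses, none lower, and a median of 0.72, above all random lists. Usp18 (2.37), Isg15 (2.20), Oas1a (2.18) and Rtp4 (2.17) led it. Among members below background on 1 array and left out, Cxcl10 was at -1.22 or lower and Oas2 at 1.16 or higher. For Isg15 the normalised values were 3.21 in WT control, -0.01 in WT LDL, 3.06 in L2AKO control and 2.04 in L2AKO LDL. Cholesterol genes had a median of 0.07 in this difference, inside the random range. Lymphocyte (0.54, 4 measured), endothelial (0.45, 9 measured) and mesothelial and epithelial markers (0.36, 7 measured) also stood above the random range, the first and second at -0.21 and -0.50 with no filter on dim probes. Antigen presentation genes had a median of 0.29, cell cycle genes 0.26 and ribosomal protein genes 0.30, the last below 0 after quantile normalisation, after normexp and in the authors' deposited values. Lysosome genes (0.08) stood above the random range as well, and p53 target and apoptosis genes (-0.15) were the only list below it.

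Of 12492 genes, 174 were at least 2-fold higher in the difference of responses and 90 lower, and 9 of 37 lists stood outside the random range. Higher genes made up 65.9%, against 79.1% with median scaling, 83.3% after normexp and 84.5% in the authors' deposited values, but 53.2% among genes above background on at least 1 array and 41.7% with no filter on dim probes. Among the named genes outside the interferon list Iqsec3 (3.83), Oas1d (2.67), Tlr7 (2.40) and Col3a1 (2.27) were highest, and Krtap1-4 (-3.32), Lpar4 (-3.19) and the peptide hormone gene Cck (-1.68) lowest. Of 14 other probes of the higher genes, 4 were at least 1.5-fold higher.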

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

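The tests of the interferon list against random lists and without LDL, the spike-in test, the comparison of cell cycle genes on both pairs of arrays, the subtraction of chromosome medians, the bounds for other probes of interferon genes, the count of members without such a probe, and the reading of the dim-gene share against the first slide and the brighter genes were chosen after the result was seen. The subtraction followed a test set beforehand, that every chromosome median lie within 0.3 of that of all genes, which chromosomes 7, 12, 18 and X did not meet without LDL. Some named genes and lists differed in opposite directions in the groups compared, and these differences were not tested, since each group had 1 array. With LDL, Cck differed by 0.84 in WT and -0.84 in L2AKO, Krtap1-4 by 2.07 and -1.25, and Mroh1 by 0.81 and -0.66. Krtap1-4 (-4.31) and Cck (-3.72) were dim in L2AKO with LDL, where the lowest normalised value well above background was -5.08. Endothelial markers had medians of -0.32 in WT and 0.23 in L2AKO (-0.13 with no filter on dim probes), and mesothelial and epithelial markers of -0.26 and 0.33. Between genotypes, Iqsec3 differed by -1.02 without LDL and 2.81 with LDL, and Lpar4 by 1.66 and -1.53.

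Interferon response genes were lower with LDL by more in WT than in L2AKO. The median of 0.72 lay above 0.10, the upper end of the central 95% of random lists matched on level. This comparison had already set the list apart, so it is no separate test. A difference between slides that follows the signal level is argued against by the range of this median over the alternatives, 0.60 to 0.82. These include cyclic loess and quantile normalisation. A higher interferon state of the WT control array alone was predicted to put the list lower in L2AKO without LDL, and its median there was 0.11. With LDL the genotype median of this list was 1.33, across slides. A difference between the lines of that size could mask such a state, so the value without LDL does not decide it. For genes with another probe, an effect of the second slide on single probes is argued against by 5 of 5 other probes above 0, with Ddx58 at 0.45 and Irgm1 at 0.03 measured on all arrays, and Isg15 at 2.32, Xaf1 at 2.32 and Oas1a at 2.05 or higher, where WT LDL was below background. For the other 23 measured members, such an effect cannot be told apart from the genotype, since they have no such probe. A weaker damping of interferon genes by LDL in the L2AKO line stays open as a hypothesis, and rests on 1 array per group, with the L2AKO LDL array alone on its slide.

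More genes were 2-fold higher with LDL in L2AKO (121) than in WT (32). Of 8 spike-ins, 7 lay outside the range of the first slide. Their shifts were -1.16 on the dimmest and 0.04 on the brightest, while n11 and n9, close in level, stood at -0.52 and 0.62. A shift that follows the signal level alone would not part n11 from n9, but this rests on these spike-ins and 1 array. The spike-ins do not tell how much of the shift of other probes is probe-specific and how much follows the level. A probe-specific effect may account for many of the genes higher in L2AKO, since 15.4% of other probes of these genes were at least 1.5-fold higher. Dim probes uncovered by a lower background were predicted to hold over 50% of them, and 66.1% did lie among the dimmest 25% of measured genes. That share was 81.2% in WT on the first slide, and among the brighter genes 41 were still higher in L2AKO against 6 in WT, which argues against dim probes as the whole cause. A larger response in the L2AKO line stays open.

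Cell cycle genes were lower and genes of chromosome 12 higher in L2AKO than in WT. Array noise is argued against by the cell cycle list, with 27 of 27 members on the same side on separate pairs of arrays. Chromosome 12 genes had a median 0.91 above that of all genes without LDL, and 87.0% of its 416 measured genes lay above. A few genes cannot set a median, so this share describes how widely the shift was spread and is no separate test. Chromosome 12 was cut by gene order into 4 stretches of equal gene number. Its lowest stretch was still 0.84 above all genes without LDL and 0.80 with LDL, across slides. Another number of copies of the whole chromosome in one line could give this. Direct dosage of genes on shifted chromosomes does not account for the cell cycle list, whose members lie on 14 chromosomes. The median of that list was -2.78 after chromosome medians were subtracted. An indirect effect of such shifts on genes of other chromosomes was not tested. Whether the knockout or another difference between the lines is the source cannot be told apart with 1 line per genotype.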

How the results depend on the processing

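The removal of the dimmest 25% of measured genes was chosen after the data were seen. No paired analysis was possible because each group had 1 array and the results come from no test. The slide could not be fitted as a block, since the second slide held 1 array, and without that array 3 of the 5 comparisons have no value. Under the 4 other scalings and in the authors' deposited values, none of the 1645 values of named genes at least 2-fold apart took the other direction, while 673 of them moved by more than 0.08, the spread of a difference between repeated spots. Median scaling and scaling over probes above background moved a comparison's genes together, by at most 0.20, so they could not turn a 2-fold difference. All of these settings rescale the same 4 arrays, so the unchanged directions say nothing about replication. The filters keep a gene's value and normexp was part of the naming rule, so neither tests these directions. The median of the cholesterol list stayed between -2.15 and -1.93 with LDL in WT and between -1.93 and -1.63 in L2AKO, that of cell cycle genes between genotypes without LDL between -2.77 and -2.22, and that of interferon genes in the difference of responses between 0.60 and 0.82. The number of lists outside the random range stayed within 1.5 times throughout.

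Counts of genes at least 2-fold apart that moved by more than 1.5 times are given as higher and lower. After normexp they were 8 and 84 for LDL in WT, 49 and 73 for LDL in L2AKO, and 75 and 15 for the difference of responses, with 884 lower between genotypes with LDL. In the authors' deposited values they were 9 and 86, 67 and 78, and 98 and 18 for the same 3 comparisons. Neither set subtracts background as the main values do, and the cause was not tested. With genes above background on at least 1 array, which adds genes, counts were 254 and 348 for LDL in WT, 373 and 392 for LDL in L2AKO, 1455 and 1627 between genotypes without LDL, 1672 higher with LDL, and 723 and 635 for the difference of responses, and the LDL responses correlated with 0.22. With no filter, which adds values below background, they were 550 and 807, 523 and 1077, 1845 and 2138, 1887 and 2661, and 1073 and 1502 for the 5 comparisons. The correlations were then 0.10 for the LDL responses and 0.71 for the genotype differences, and the median of all genes between genotypes with LDL moved by -0.22. Without the dimmest 25%, which removes genes, they were 6 and 79, 41 and 66, 555 and 627, 663 and 797, and 70 and 14.

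Some list medians changed sign, and the cause was not tested. Heat shock proteins with LDL in WT (-0.01) were at 0.0499 when scaled over probes above background on all arrays, 0.0298 after quantile normalisation, 0.0152 after cyclic loess, 0.0305 after normexp, 0.0365 in the authors' deposited values and 0.0036 with the mean of a gene's probes. Ribosomal proteins were at -0.0246 after quantile normalisation and -0.0069 after normexp with LDL in L2AKO, and in the difference of responses (0.30) at -0.01 after quantile normalisation, -0.0541 after normexp and -0.0286 in the authors' deposited values. Among genes above background on all 4 arrays, matrix turnover with LDL in WT was at -0.0269 and adventitial fibroblast markers between genotypes without LDL at -0.0757. Growth factor, Wnt and Notch genes without LDL were at -0.12 with genes above background on at least 1 array and with no filter. With no filter, NRF2 genes (-0.0008) and matrix turnover (-0.0269) changed sign with LDL in WT, endothelial markers with LDL in L2AKO (-0.13) and in the difference of responses (-0.50), lymphocyte markers in that difference (-0.21), and adipocyte markers without LDL (-0.0443). With the mean of a gene's probes, chaperone-mediated autophagy genes with LDL in WT were at -0.0209.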

Other observations

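The Hox test and both chromosome 12 tests were written before their values were seen; the lists of acute phase genes, glutathione S-transferases and the Dlk1-Meg3 region were drawn up after leading members had been seen. Acute phase and complement genes were lower with LDL in both lines, with 13 of 18 measured members lower in WT (median -0.99) and 16 of 18 in L2AKO (median -1.39). Complement C3 differed by -1.14 in WT and -1.15 in L2AKO, Cfb by -2.85 and -2.30, Chil1 by -2.91 and -2.96, and the protease inhibitor Slpi by -2.23 and -2.30. Between genotypes the list had 10 of 20 members higher in L2AKO and 3 lower without LDL (median 0.64), and 9 of 18 higher and 2 lower with LDL (median 0.57). Of the glutathione S-transferases, 4 of 22 were higher with LDL and 1 lower in WT (median 0.17), and 3 of 21 were higher and none lower in L2AKO (median 0.09). Gstm1, 0.54 higher in WT and 0.51 in L2AKO, did not reach 1.5-fold, and the lower member in WT was Gstt2 (-0.68).

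Of 20 chromosomes, 15 had a median genotype difference outside the central 95% of random gene sets of the same size without LDL and 17 with LDL, and only chromosome 12 was cut into stretches. Relative to all genes, the furthest medians without LDL were 0.91 on chromosome 12, 0.35 on chromosome 18, -0.31 on chromosome 7 and -0.52 on chromosome X, and with LDL these were 0.85, 0.31, -0.30 and -0.65, with chromosome 13 also at -0.30. Over 20 chromosomes the medians without and with LDL, from separate arrays, correlated with r = 0.99. Lamp2 lies on chromosome X. The gene table's assembly was used for chromosome names and gene order only.

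Hox genes mark the position of a tissue along the body axis. Of 18 measured Hox genes, 4 were at least 2-fold apart without LDL, all higher in L2AKO. These were Hoxc6 at 4.04, Hoxb7 at 1.82, Hoxb8 at 1.81 and Hoxc4 at 1.73. Over all genes, 15.77% were at least 2-fold apart in this comparison, and the Hox median of 0.12 stayed inside the random range. Hoxa10, Hoxd3, Hoxd4, Hoxd8 and Hoxd9 were well above background on both WT arrays and on neither L2AKO array, and Hoxa6 and Hoxc8 on both L2AKO arrays and neither WT array. Lines grown from different stretches of the aorta could give such values, and the 4 of 18 measured genes do not decide it.

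In the imprinted Dlk1-Meg3 region of chromosome 12, the noncoding genes Meg3 (5.63) and Mirg (4.56) were higher in L2AKO without LDL, the coding gene Dlk1 was 3.26 higher and Begain 1.93 higher. Dio3 was well above background in WT control and not in L2AKO control. Both noncoding genes had been seen when the list was drawn up and 0 others were measured, so a regional difference between the lines was not tested on other noncoding genes.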
